A study of Mus musculus with 9 samples.

How the data were processed

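The series measured RNA in 9 samples of bone marrow-derived macrophages from C57Bl/6 mice, in 3 groups of 3: vehicle then vehicle (Veh_N), vehicle then LPS (Veh_LPS) and D2HG octyl ester then LPS (D2HG_LPS), with 1 h for the first treatment and 24 h for the next. Groups and replicate numbers come from the sample titles and treatment labels. Per the labels' protocols, RNA was taken with a Qiagen RNeasy kit and made into strand-specific libraries with the KAPA mRNA HyperPrep kit. STAR 2.5.2b and DESeq2 (no version) are named per the submitters' processing notes, which list the mouse builds mm10 and mm9 without saying what each was used for. The counting program, its annotation and its strand setting are not given in the sources used here, so no coordinates are printed.

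The authors deposited a table of raw read counts, 1 column for each library and 1 line for each of 35745 RefSeq transcripts. Of these transcripts 35440 were matched to gene symbols through a RefSeq gene table and 188 through GENCODE vM21 identifiers, and 117 were not matched. The unmatched transcripts held 0.676% to 2.37% of the counts of a library, mostly from 1 noncoding transcript (0.438% to 2.25%), and stayed out of library sizes and tests. In 6089 genes several transcripts were listed. Among the 3961 of these with at least 100 counts, the median ratio of the next transcript's count to the highest was 0.992, and in 86.6% both counts differed by at most 10%, so reads were counted in each isoform that holds them. The transcript with most counts was therefore taken for each gene, and the sum of isoforms was an alternative. This gave 24445 genes and 9451258 to 13759935 counts per library, which limits the precision for genes with few counts. Intervals and floors cover counting error only, since the counts carry no molecular identifiers.

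Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (11622 genes), scaled by TMM, and fitted by glmQLFit with robust=TRUE over all 9 libraries, with group as the only term. The 3 comparisons (Veh_LPS over Veh_N, D2HG_LPS over Veh_LPS, D2HG_LPS over Veh_N) were tested with glmQLFTest, two-sided, and called at a Benjamini-Hochberg adjusted p below 0.05 within the comparison. TMM factors were 0.831 to 0.887 in the LPS groups and 1.338 to 1.351 in Veh_N. The common biological coefficient of variation was 0.105. Standard errors were taken as the fold change over the square root of the F statistic. Levels are given as TMM-scaled CPM. Where a named gene had 1 to 3 counts per library on average in a group, the ratio of summed counts was given an exact binomial interval (95%). A gene with 0 counts in all libraries of a group was compared with a floor of 3 counts per library. Replicates differed by more than counting noise in every pair (chi-square per degree of freedom 2.78 to 23.7), so none was taken as a copy of another.

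The comparisons, the tests, 42 lists of genes, the rule for named genes and the first set of alternatives were fixed before the data were examined. The lists came from textbook knowledge of inflammation, metabolism, stress responses, macrophage identity and markers of other cell types that a marrow culture could hold. The 37 lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 3, preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. Members called over all genes and members called after adjustment over the list alone were counted. The rule for named genes took the 10 rising and 10 falling called genes of largest fold change with a mean log2 CPM of at least 3 and no overlap between the groups' libraries, leaving out predicted genes, then up to 4 members of smallest p from each list, and 17 genes of the LPS response and of hydroxyglutarate metabolism. Some genes that the rule names are not reported here, and genes named outside it are said to be.

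The edgeR, limma-voom and DESeq2 tests, the replicate block, the fit of only 2 groups, camera with the preset correlation and the length correction were tested on simulated data for D2HG_LPS against Veh_LPS, drawn from the real means and library sizes, with 200 genes changed. The edgeR test ran on 11529 genes. It recovered 51.5% of 66 genes changed 1.5-fold, 79.1% of 67 changed 2-fold and 87.7% of 65 changed 4-fold, and called 15 of 11331 unchanged genes. DESeq2 recovered 52.2% of 67 changed 1.5-fold, 79.1% of 67 changed 2-fold and 86.4% of 66 changed 4-fold on 11622 genes, and called 19 unchanged ones. In this draw unchanged genes made up more than the nominal 0.05 of the calls of either test. The 20 members of 1 list, changed 1.5-fold in another draw (11543 genes), were called by camera, and 0 of the other lists were called beside it. Genes were drawn independently of each other, so this draw does not test camera where members vary together. Estimated correlations in the real data reached 0.67, for the interferon-inducible GTPases.

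The first set of alternatives was DESeq2 1.42.0, RLE and upper-quartile scaling, no low-count filter, a filter of 10 CPM in at least 3 libraries, fits of only the groups compared, the replicate number as a block, glmTreat against a fold change of 1.5, limma-voom, robust=FALSE, leaving out each library in turn, and for lists an estimated correlation and fry. Added after seeing the data were scaling by library totals alone, corrections for transcript length and for GC content (each library's smooth trend, lowess span 0.3, as an offset), sums of isoforms, and leaving out Veh_LPS replicate 3 and Veh_N replicate 1 together. Length and GC content were known for 98.4% of tested genes. For the comparison of the ester with the LPS response, 100 data sets with an unchanged ester group were simulated. In each, the counts of all 9 libraries were drawn anew, each gene on its own, and both comparisons shared the drawn Veh_LPS libraries. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 joined the tables and drew the figures.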

Results

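Bone marrow-derived macrophages of C57Bl/6 mice, which are grown in culture from marrow precursors, were profiled by RNA sequencing in 9 libraries. The 3 groups held 3 libraries each. Veh_N cells received vehicle for 1 h and vehicle again for 24 h. Veh_LPS cells received vehicle for 1 h and then lipopolysaccharide (LPS), a bacterial cell wall component sensed by Toll-like receptor 4, for 24 h. D2HG_LPS cells received the octyl ester of D-2-hydroxyglutarate (D2HG) for 1 h before 24 h of LPS. D2HG is a metabolite close in structure to alpha-ketoglutarate, and esters of this kind are used to carry acids across the cell membrane. The design held no group given the ester without LPS and none given an octyl ester of another acid. Dose is not given in the sources used here. With 1 transcript taken per gene, depth was 11659437, 13209786 and 11539635 counts in the D2HG_LPS libraries, 11926438, 11049012 and 13759935 in Veh_LPS and 10831619, 12619702 and 9451258 in Veh_N. Of 24445 genes, 16158 had counts and 11622 were deep enough to test. The first principal component held 91.5% of the variance and the next one 2.9%. The labels do not say whether replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

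The comparison of Veh_LPS with Veh_N shows what 24 h of LPS changed after vehicle. Inflammatory cytokine genes rose as a group, with 19 of 19 measured members called higher over all genes and 19 adjusted over the list alone. Il6, the gene of a central inflammatory cytokine, went from 0.184 ± 0.0820 to 364 ± 61.2 CPM (counts scaled to a common library size, mean ± SD, n = 3), a log2 fold change of 10.89 ± 0.21 (SE). Il12b, a subunit of interleukin-12 and interleukin-23, rose by a log2 fold change of 10.64 ± 0.23. Both had 8 counts in all over the Veh_N libraries, so counting alone gives 95% intervals of 10.01 to 12.20 for Il6 and 9.76 to 11.95 for Il12b. Other members rose as well, Il1b by 9.36 ± 0.21, Tnf by 7.75 ± 0.11 and the anti-inflammatory Il10 by 5.28 ± 0.15. The median member rose by 7.26, or by 6.59 with the 2 genes that had no counts in Veh_N held at their lower bound. Inducible nitric oxide synthase Nos2 (10.49 ± 0.12) and Acod1 (10.34 ± 0.14), whose enzyme makes itaconate, rose by similar amounts, as did the prostaglandin enzyme Ptgs2 (10.45), the endothelin precursor Edn1 (10.40, but 12.14 without Veh_N replicate 1) and the serpin Serpina3g (10.85). Chemokine genes were higher in 15 of 16 cases, by either adjustment, including Cxcl9 (10.53 ± 0.13), Cxcl10 (10.34 ± 0.14), Ccl5 (10.19) and Ccl2 (5.48). Bcl2a1a, a survival gene of the Bcl2 family, had 0 counts in every Veh_N library and 20.2 CPM in Veh_LPS, at least 97.8-fold higher against a floor of 3 counts per library. Bcl2a1a and Serpina3g have near-identical neighbours in the genome, so their counts may be shared with these.

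Interferon-stimulated genes were higher in 42 of 42 cases, such as Mx1 (7.63) and Ifi205 (9.18), and 16 of 17 interferon-inducible GTPase genes were higher, such as Gbp5 (8.22). All 19 genes of the major histocompatibility complex class I pathway were higher, among them the peptide transporter Tap1 (3.84) and its transcriptional activator Nlrc5 (3.97). Of 14 class II and costimulation genes 11 rose, led by Cd40 (8.18), and 1 fell. Of 25 adhesion and matrix protease genes 18 rose, for example Mmp14 (7.56) and Icam1 (5.04), and 5 fell. Of 14 inflammasome genes 10 rose, for example Nlrp3 (3.47) and Casp4 (3.78), and 4 fell. Of 15 iron and metal genes 10 rose, such as the siderophore-binding Lcn2 (4.57), and 3 fell, among them the iron exporter Slc40a1 (-4.26). Of 8 dendritic cell markers 6 rose, including Fscn1 (6.82) and Ccr7 (4.06), and 1 fell. Of 8 neutrophil markers 6 rose, such as Csf3r (1.67), and 1 fell, and of 7 osteoclast markers 2 rose and 5 fell, such as Atp6v0d2 (-2.02), though neither list was called (camera, Benjamini-Hochberg adjusted p = 0.103 and 0.287). Counts adjusted over the list alone were the same for each list of this paragraph so far. Of 13 stromal and endothelial markers 4 had enough counts to test, and all 4 rose, among them Kdr (3.88) and Pecam1 (4.83). A marker with few counts in Veh_N could pass the filter only through the LPS libraries, so this count is not independent of the filter. Of 4 lymphoid markers with enough counts 1 rose and 3 fell.

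Glycolysis genes were higher in 17 of 21 cases and lower in 3, with the transporter Slc2a6 at 4.98 and the regulator Pfkfb3 at 3.28. Of 26 tricarboxylic acid cycle genes 16 were higher and 4 lower, by smaller amounts (Cs 0.73, Idh3a 0.90, list median 0.40). Of 65 nuclear genes of oxidative phosphorylation 33 were higher (32 adjusted over the list alone) and 1 lower, with a median of 0.43. Integrated stress response genes rose in 14 of 22 cases and fell in 3 (4 adjusted over the list alone), with Nupr1 at 3.41 and the asparagine synthetase gene Asns at 2.20. Heat shock genes rose in 10 of 13 cases and fell in 2, with Hspa1a at 4.55 and Hspa1b at 4.74, a near-identical pair whose counts may be shared. Cell cycle genes fell in 28 of 40 cases and rose in 9, with Cdc20 at -3.43 and Kif20a at -2.55. Among genes of hydroxyglutarate metabolism, D2hgdh, which encodes the dehydrogenase that oxidises D2HG, fell from 10.6 ± 0.681 to 3.76 ± 0.370 CPM (-1.50 ± 0.15). Idh1 fell by 1.58 on the log2 scale, Phgdh rose by 1.80 and Adhfe1 by 2.97, and Idh2 was not called (0.06 ± 0.09). Hif1a rose by 1.40. The largest falls among well-expressed genes were those of Fam214a (-7.06, 95% counting interval -8.24 to -6.18 from 9 counts under LPS), Slc26a11 (-7.05), the phosphatidate phosphatase Lpin1 (-6.82), Tcp11l2 (-6.64, and -7.27 without Veh_LPS replicate 2), the lipid receptor S1pr1 (-6.15), Zfp395 (-5.93), the chemokine receptor Cxcr4 (-5.82), Plekhg3 (-5.77), Sesn1 (-5.69) and the myeloid transcription factor Cebpa (-5.61).

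By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4071 genes were higher and 4516 lower under LPS at adjusted p below 0.05, 73.9% of those tested, and 2069 and 2477 of them differed at least 2-fold. Of the 37 lists tested with camera, 18 were called, 17 higher and 1 (cell cycle) lower. The cytokine list was called at adjusted p = 2.47e-10 and stayed called with an estimated correlation, at Benjamini-Hochberg adjusted p = 0.0314. The other 17 were not called with an estimated correlation, at Benjamini-Hochberg adjusted p = 0.112 for chemokines, 0.233 for interferon-stimulated genes, 0.255 for the GTPases and the inflammasome, 0.19 for class I genes, iron genes, dendritic markers, the tricarboxylic acid cycle and heat shock, 0.104 for class II and for anti-inflammatory feedback genes (18 of 22 higher), 0.23 for adhesion, 0.314 for glycolysis, 0.657 for oxidative phosphorylation, 0.382 for the integrated stress response, 0.336 for the cell cycle and 0.233 for the Toll-like receptor pathway (19 of 26 higher). The direction of small changes rested on the scaling. The share of calls that were higher was 47.4%, against 33.2% with upper-quartile scaling, which shifted the median gene by -0.32, and 21.8% with library totals alone, which shifted it by -0.67, and calls given here are relative to the main scaling. With library totals alone the lists of the tricarboxylic acid cycle (camera, Benjamini-Hochberg adjusted p = 0.877), oxidative phosphorylation (0.0544), heat shock (0.0544) and the cell cycle (0.0508) were no longer called, and Idh2 turned to -0.61. The call of the tricarboxylic acid cycle was also lost without Veh_N replicate 1, where 17 lists were called, and with the GC correction (camera, Benjamini-Hochberg adjusted p = 0.0636). The other 19 lists were not called, at camera adjusted p from 0.0567 to 0.958 after Benjamini-Hochberg adjustment.

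The comparison of D2HG_LPS with Veh_LPS addresses the question of the series, what the ester changes in the response to LPS. Slc16a6, a gene of the monocarboxylate transporter family, rose most among well-expressed genes, from 8.17 ± 1.32 to 65.6 ± 7.46 CPM (mean ± SD, n = 3), a log2 fold change of 3.0 ± 0.13 (SE). Arrdc3, an arrestin-domain gene, rose by 2.62 ± 0.18. Hilpda, which encodes a lipid droplet protein that inhibits triglyceride breakdown, went from 4.54 ± 0.395 to 18.1 ± 1.23 CPM (2.00 ± 0.14). The growth factor genes Pdgfb (1.51 ± 0.18) and Vegfa (1.32 ± 0.13) rose, as did the inhibitory receptor Cd300a (1.35 ± 0.12), the cannabinoid receptor Cnr2 (1.30), the formin Fmnl3 (1.26) and the transcription factor genes Klf10 (1.21) and Elk3 (1.19). The largest falls among well-expressed genes were those of the formyl peptide receptor Fpr1 (-1.16 ± 0.14) and of Cxcl9, a chemokine induced by interferon-gamma, which went from 851 ± 34.9 to 386 ± 3.76 CPM (-1.14 ± 0.07). Nox1 (-1.03), Lox (-1.01), the cholesterol exporter Abca1 (-0.98), the cytokine Tnfsf15 (-0.94), Fpr2 (-0.90), Gpr85 (-0.90) and Fgd4 (-0.88) also fell. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 1.61e-07 for Slc16a6, 1.22e-05 for Arrdc3, 1.58e-05 for Hilpda, 2.78e-04 for Vegfa, 4.9e-06 for Cxcl9 and 9.75e-04 for Fpr1. The call of Nox1 was lost without any single LPS-treated library or Veh_N replicate 2 (-1.23 to -0.79 over all alternatives), those of Lox (-1.11 to -0.83) and Fpr2 (-1.03 to -0.64) without any single D2HG_LPS library, and that of Fgd4 (-0.99 to -0.71) without any single LPS-treated library but Veh_LPS replicate 2, or without Veh_N replicate 2. Ranges given beside a lost call, here and below, run over all alternatives, not only the fits that left out 1 library. Slc16a6 lies beside a predicted gene with a similar change (Gm45916, 2.96, named after its value was seen), and the strand setting of the counting is not given in the sources used here, so their reads may be shared.

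The inflammatory cytokine list, the one tied most closely to the question of the series, was called lower by camera (Benjamini-Hochberg adjusted p = 3.29e-04, median -0.33), and with an estimated correlation the call was lost (adjusted p = 0.123). Of 19 measured members 4 fell over all genes and 7 adjusted over the list alone. Il6 fell from 364 ± 61.2 to 225 ± 7.42 CPM (-0.69 ± 0.11), Il12b from 307 ± 50.6 to 175 ± 18.9 CPM (-0.81 ± 0.12), and Tnfsf15 (-0.94) and Il18 (-0.36) fell too. Other central genes of the LPS response were not called, with Il1b at 573 ± 76.6 and 579 ± 95.9 CPM (0.01 ± 0.12), Tnf at 1743 ± 134 and 1634 ± 62.9 CPM (-0.09 ± 0.08), Il10 at -0.27 ± 0.11, Nos2 at -0.20 ± 0.07 and Acod1 at -0.12 ± 0.09. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 0.00571 for Il6, 0.00326 for Il12b, 0.973 for Il1b and 0.63 for Tnf. Among 16 chemokine genes 4 fell, namely Cxcl9, Ccl8 (-0.84), Ccl12 (-0.70) and Ccl3 (-0.35), while adjusted over the list alone 4 were lower and 2 higher. Ccl2 (-0.01 ± 0.16) and Cxcl10 (-0.02 ± 0.09) were not called, nor was the chemokine list (camera, Benjamini-Hochberg adjusted p = 0.134). Interferon-stimulated genes had a median of -0.15, with 1 of 42 called lower by either adjustment (Trim21, -0.40), and the list was called (camera, Benjamini-Hochberg adjusted p = 0.00264), a call lost with an estimated correlation (adjusted p = 0.615) and by directional fry (0.506). Of 17 interferon-inducible GTPase genes none was called by edgeR over all genes, 5 were lower adjusted over the list alone, 7 were lower at an unadjusted p below 0.05, and DESeq2 called 4 lower and limma-voom 2. Their list was called too, with a median of -0.28 and Gbp6 at -0.58 ± 0.15 (camera, Benjamini-Hochberg adjusted p = 0.00184), a call lost with an estimated correlation (adjusted p = 0.511) and by directional fry (0.316). The call of Il6 was lost without D2HG_LPS replicate 1 (-0.67), that of Il18 without any single LPS-treated library or Veh_N replicate 2 (-0.46 to -0.28 over all alternatives), that of Ccl3 without any single LPS-treated library but Veh_LPS replicate 3, or without Veh_N replicate 2 (-0.45 to -0.29), and that of Trim21 without any single LPS-treated library but Veh_LPS replicate 2, or without Veh_N replicate 2 (-0.44 to -0.33).

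**Figure D1:**
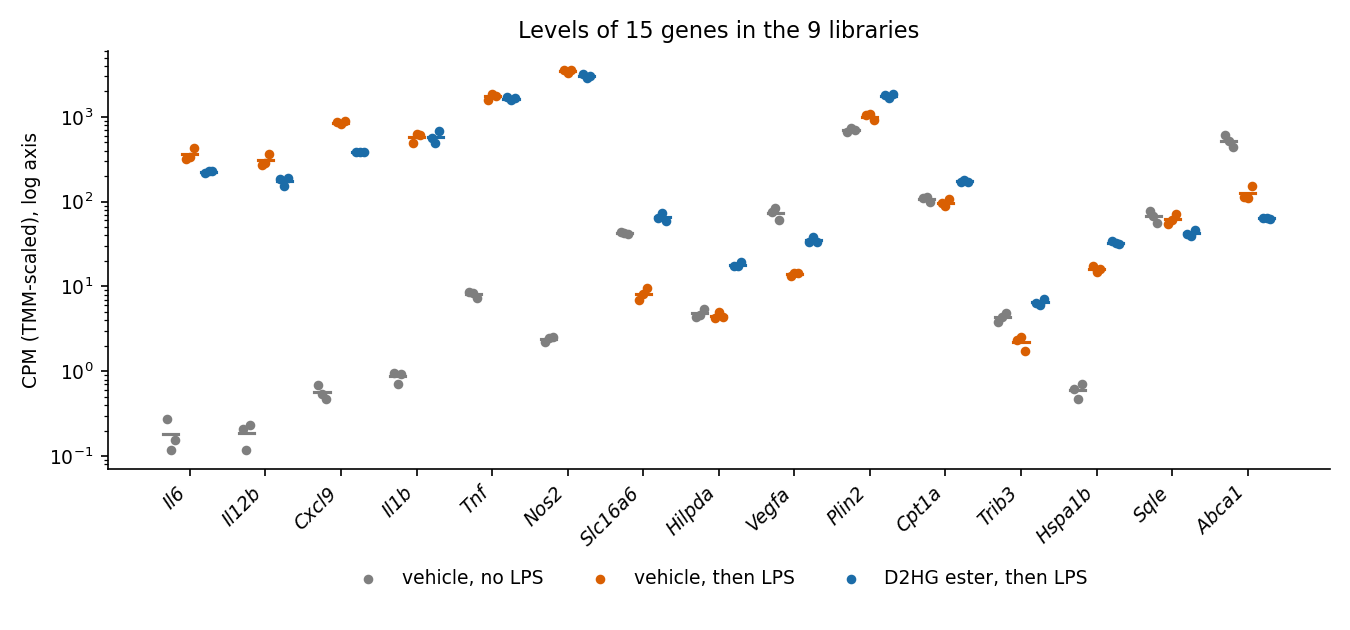
Levels of 15 genes in TMM-scaled CPM (log axis) in the 9 libraries, with a point for each library, a bar at the mean of each group of 3, and colours for the groups. Il6, Il12b and Cxcl9 lie lower in D2HG_LPS than in Veh_LPS, Il1b and Tnf overlap, and Slc16a6 goes from 8.17 to 65.6 CPM.

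Of the lists of lipid metabolism, cholesterol synthesis was called lower, with 22 of 23 members at a negative fold change, a median of -0.35, 4 called lower over all genes and 15 adjusted over the list alone. Among these was Sqle (-0.56), which encodes squalene epoxidase. The camera test gave a Benjamini-Hochberg adjusted p of 2.54e-10, and the call stayed with an estimated correlation (adjusted p = 0.0415). Liver X receptor targets were not called as a list by camera (Benjamini-Hochberg adjusted p = 0.278), but directional fry called them lower (Benjamini-Hochberg adjusted p = 0.0124). Of these targets 3 of 15 fell by either adjustment. They were the sterol exporters Abca1 (-0.98 ± 0.14) and Abcg1 (-0.53 ± 0.08) and the receptor-degrading ligase gene Mylip (-0.52). The lipid droplet coat gene Plin2 rose from 1008 ± 88.1 to 1772 ± 89.6 CPM (0.81 ± 0.08), and Cpt1a, which encodes the enzyme that commits fatty acids to mitochondrial oxidation, from 97.5 ± 9.58 to 174 ± 6.95 CPM (0.83 ± 0.09). Both belong to the list of fatty acid oxidation and its regulated genes, of which 2 of 28 rose by either adjustment, with a median of 0.14 (camera, Benjamini-Hochberg adjusted p = 0.00357), a call lost with an estimated correlation (adjusted p = 0.511) and by directional fry (0.0512). The list of fatty acid synthesis and storage was not called (camera, Benjamini-Hochberg adjusted p = 0.135), and of its 20 members Hilpda rose and the fatty acid synthase gene Fasn fell by 0.56 on the log2 scale, while adjusted over the list alone 1 was higher and 4 lower. The call of Sqle (-0.64 to -0.45 over all alternatives) was lost without any single LPS-treated library or Veh_N replicate 2, and that of Mylip (-0.61 to -0.42) without any single LPS-treated library but Veh_LPS replicate 1, or without Veh_N replicate 2. That of Fasn (-0.64 to -0.43) was lost without D2HG_LPS replicate 2 or 3 or Veh_LPS replicate 1.

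Of 4 lists of stress responses, heat shock, the integrated stress response and NRF2 targets were called higher, the latter 2 not with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.0415, 0.44 and 0.511). The unfolded protein response list was not called (0.608), and edgeR called none of its 20 members by either adjustment, nor did DESeq2 or limma-voom, while 2 were higher and 1 lower at an unadjusted p below 0.05. Of 22 genes of the integrated stress response, which is driven by the transcription factor Atf4, 5 rose over all genes, while adjusted over the list alone 12 were higher and 1 lower. Chac1, which encodes a glutathione-degrading enzyme, rose by 1.98 ± 0.32, the pseudokinase gene Trib3 from 2.22 ± 0.418 to 6.57 ± 0.582 CPM (1.57 ± 0.20), Sesn2 by 0.92, Atf4 itself by 0.49 and Nupr1 by 0.48. The list median was 0.27 (camera, Benjamini-Hochberg adjusted p = 8.21e-07). All 13 heat shock genes had a positive fold change, with a median of 0.18, and 4 rose over all genes and 6 adjusted over the list alone. These 4 were Hspa1a (1.03 ± 0.13) and Hspa1b (1.03 ± 0.11), whose near-identical sequences may share counts, Hsph1 (0.53) and Dnajb1 (0.42). The heat shock list had a Benjamini-Hochberg adjusted p of 1.88e-05 by camera. Of 26 targets of the antioxidant regulator NRF2, 3 rose over all genes, namely the sulfiredoxin gene Srxn1 (0.84 ± 0.11), the glutathione reductase gene Gsr (0.36) and Sqstm1 (0.37), while adjusted over the list alone 5 were higher and 1 lower. Their list was called narrowly (camera, Benjamini-Hochberg adjusted p = 0.0348). It lost its call by directional fry (Benjamini-Hochberg adjusted p = 0.141), with the length correction (camera, 0.0978), without D2HG_LPS replicate 1 or 3 or Veh_LPS replicate 1, and when Veh_LPS replicate 3 and Veh_N replicate 1 were left out together (camera, Benjamini-Hochberg adjusted p = 0.0518). The call of Chac1 was lost without D2HG_LPS replicate 1 (1.78), and DESeq2 gave it no adjusted p through its filter on low counts (1.96). Those of Sesn2 (0.79 to 1.10 over all alternatives) and Atf4 (0.44 to 0.55) were each lost without D2HG_LPS replicate 1 or Veh_LPS replicate 1, and also without D2HG_LPS replicate 2 for Sesn2 and replicate 3 for Atf4. Those of Gsr (0.32 to 0.42) and Sqstm1 (0.32 to 0.43) were lost without any single LPS-treated library or Veh_N replicate 2, and that of Nupr1 (0.40 to 0.55) without any of these but Veh_LPS replicate 2. Hsph1 (0.47 to 0.63) and Dnajb1 (0.35 to 0.50) lost theirs without any single LPS-treated library but Veh_LPS replicate 2, or without Veh_N replicate 2.

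**Figure D2:**
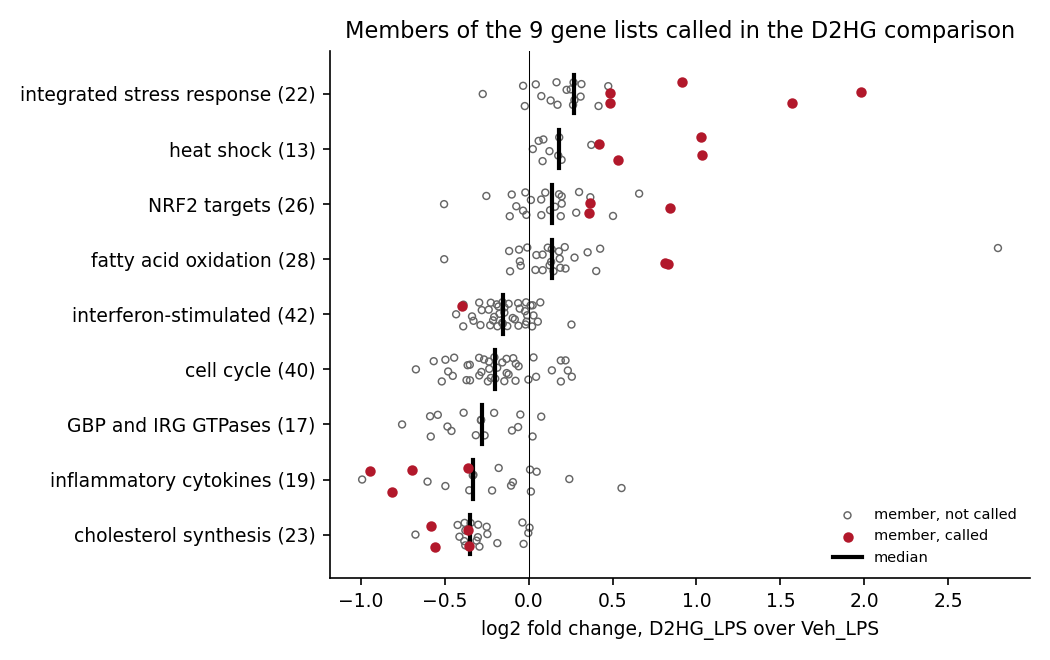
Log2 fold changes of D2HG_LPS over Veh_LPS for the members of the 9 called lists, with the number of members in brackets, filled points for genes called over all genes and a bar at the median. The median runs from -0.35 for cholesterol synthesis to 0.27 for the integrated stress response, and the open point near 2.80 is Angptl4, which had 0 counts in every Veh_LPS library, so that its fold change is not a measured size.

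The cell cycle list was called lower by camera (Benjamini-Hochberg adjusted p = 1.64e-04), a call lost with an estimated correlation (adjusted p = 0.44) and by directional fry (0.0799). Of its 40 genes 32 had a negative fold change, with a median of -0.20, and edgeR called none by either adjustment. At an unadjusted p below 0.05, 12 were lower, and DESeq2 called 2 lower and limma-voom none. Mki67 was at -0.48 ± 0.13 and Tpx2 at -0.28 ± 0.08. The other 28 lists were not called, at camera adjusted p from 0.12 to 0.998 after Benjamini-Hochberg adjustment. Hypoxia-inducible genes had 2 of 20 higher by either adjustment, Vegfa and Mxi1 (0.52), and Hif1a was not called (-0.12 ± 0.14). The call of Mxi1 was lost without any single LPS-treated library or Veh_N replicate 2 (0.47 to 0.58 over all alternatives). Of 20 genes of alpha-ketoglutarate-dependent dioxygenases, a class of enzymes that D2HG can inhibit, edgeR called the histone demethylase gene Kdm5b alone (0.65 ± 0.12), a call lost without any single LPS-treated library but Veh_LPS replicate 3 (0.61 to 0.78). Adjusted over the list alone, 1 dioxygenase gene was higher and 3 lower, while DESeq2 called 1 higher and 2 lower and limma-voom 1 higher. None of 17 genes of hydroxyglutarate metabolism was called by edgeR under either adjustment, nor by DESeq2 or limma-voom, and at an unadjusted p below 0.05 1 was higher and 2 lower. Log2 fold changes were 0.11 ± 0.17 for D2hgdh, -0.24 ± 0.10 for Idh1, 0.04 ± 0.09 for Idh2, 0.15 ± 0.13 for Phgdh and -0.53 ± 0.21 for Adhfe1. By edgeR no gene was called among 21 of glycolysis (1 lower adjusted over the list alone), 26 of the tricarboxylic acid cycle and 65 of oxidative phosphorylation. At an unadjusted p below 0.05, 1 was higher and 2 lower in glycolysis and 1 lower in each of the other lists, while DESeq2 called 1 lower in glycolysis and 1 in the tricarboxylic acid cycle, and limma-voom 1 in glycolysis. Arg1 had too few counts to test. Of markers of other cell types, 1 of 8 neutrophil genes (Csf3r, -0.45), 1 of 8 dendritic genes (Fscn1, -0.71) and the endothelial Kdr (-0.86), 1 of 4 stromal genes with enough counts, were lower, and none of 7 osteoclast genes was called by edgeR, DESeq2 or limma-voom or had an unadjusted p below 0.05. The calls of Csf3r (-0.51 to -0.38) and Fscn1 (-0.82 to -0.65) were each lost without Veh_LPS replicate 1 or D2HG_LPS replicate 3, and also without D2HG_LPS replicate 1 for Csf3r and replicate 2 for Fscn1.

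By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 134 genes were higher and 111 lower with the ester at adjusted p below 0.05, 2.1% of those tested, with a median size of 0.62 on the log2 scale. Of these, 24 and 13 differed at least 2-fold. The share of calls that were higher was 54.7%, against 34.8% of 515 with DESeq2, 40.8% of 265 with RLE size factors and 74.4% of 285 with library totals alone. The count was sensitive to single libraries. It was 64, 92 and 80 without D2HG_LPS replicate 1, 2 or 3, 86, 148 and 151 without Veh_LPS replicate 1, 2 or 3, and 501, 143 and 387 without Veh_N replicate 1, 2 or 3. Fits without a D2HG_LPS or Veh_LPS library also have less power for this contrast. A call lost there does not by itself show that the change rests on that library. In these fits 0 of the 245 genes were called in the opposite direction. Libraries differed within groups in the signal from long transcripts, with Spearman's rho of deviation and length of 0.59 for Veh_LPS replicate 3, 0.547 for Veh_N replicate 1 and 0.453 for D2HG_LPS replicate 2, against -0.612 for Veh_LPS replicate 2, -0.6 for Veh_N replicate 3 and -0.474 for D2HG_LPS replicate 3. A noncoding transcript left out of the tests held 2.075% and 2.25% of counts in Veh_LPS replicate 3 and Veh_N replicate 1, 0.438% to 0.783% in the others of these groups, and 1.713%, 1.038% and 0.52% in D2HG_LPS replicates 1, 2 and 3. Fold changes of the ester fell with transcript length across 6693 genes, which are not independent replicates (Spearman's rho -0.318, and -0.037 without Veh_LPS replicate 3). With Veh_LPS replicate 3 and Veh_N replicate 1 left out 565 genes were called, among them 98.4% of the 245, and the lists of cytokines, cholesterol synthesis, the integrated stress response and heat shock stayed called (camera, Benjamini-Hochberg adjusted p = 1.97e-04, 2.98e-10, 4.04e-05 and 1.59e-05). The NRF2 list lost its call there. These p-values use the preset correlation, and with an estimated one over all libraries cytokines (0.123) and the integrated stress response (0.44) were not called. In simulated data for this comparison, with 11529 genes tested, 51.5% of 66 genes changed 1.5-fold and 79.1% of 67 changed 2-fold were recovered, so a change of the smaller size could be missed.

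Set against the LPS response, 179 of the 245 genes called with the ester (73.1%) ran against their LPS call. Of these, 96 were raised by LPS and lower with the ester, against 38.9 for independent lists, as in Il6, Il12b and Cxcl9, and 83 were lowered by LPS and higher with the ester, against 52.1, as in Slc16a6 and Vegfa. Vegfa went from 73.3 ± 11.4 CPM in Veh_N to 14.0 ± 0.781 in Veh_LPS and 35.0 ± 2.91 in D2HG_LPS. Which side was larger turned with the scaling, with 134 lower and 64 higher by RLE size factors, 279 and 102 by DESeq2, 87 and 100 by upper quartile and 55 and 165 by library totals alone. In the same direction as LPS, 33 genes were higher with both (46.9 for independent lists), such as Hspa1a and Hspa1b, and 10 were lower with both (43.1), such as Abca1. Of the remaining genes 18 were higher and 5 lower with the ester without an LPS call. Among the 234 genes with an LPS log2 change of 5 or more, the median ester fold change was -0.22, with 34 called lower and 2 higher. The 2 comparisons share the 3 Veh_LPS libraries with opposite sign. In 100 simulated data sets with an unchanged ester group, which gave too few ester calls to compare directions (at most 2), the covariance of the fold changes averaged -0.026, against -0.181 observed, a difference of -0.155. The simulation drew each gene on its own, without the deviations that real libraries share across genes. The 3 Veh_LPS libraries cannot be split into parts of at least 2 libraries each, so part of the excess may come from the shared controls. The number of genes that ran against their LPS call was 46, 65 and 60 without D2HG_LPS replicate 1, 2 or 3, 66, 107 and 111 without Veh_LPS replicate 1, 2 or 3, and 369, 104 and 278 without Veh_N replicate 1, 2 or 3.

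**Figure D3:**
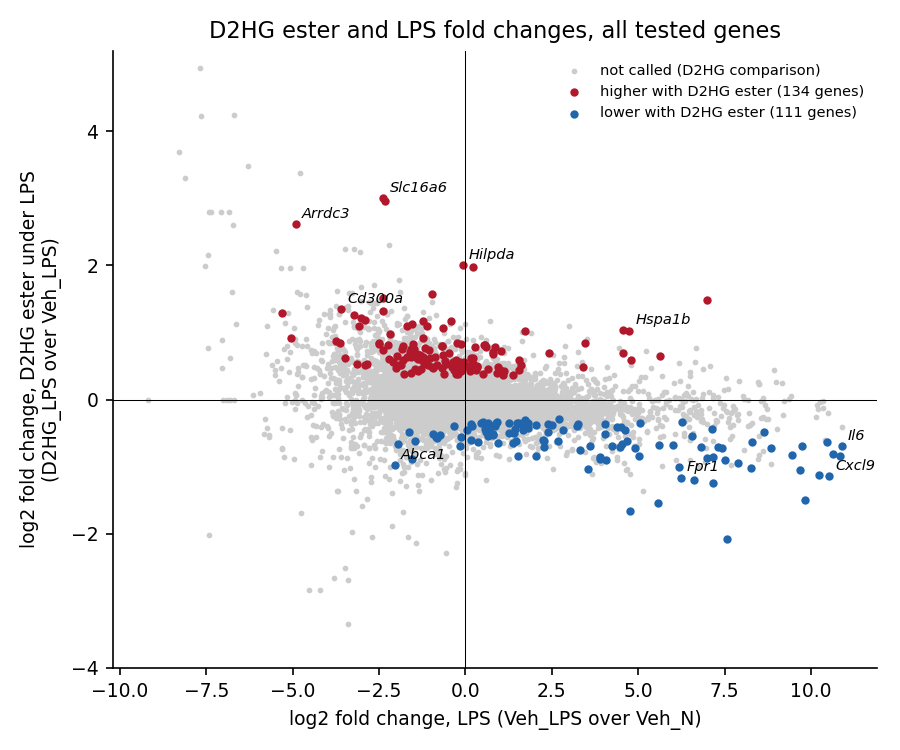
Log2 fold change with the ester (D2HG_LPS over Veh_LPS) against that with LPS (Veh_LPS over Veh_N), with a point for each of 11622 tested genes and colours for the 134 genes called higher and the 111 called lower with the ester. Most genes called lower with the ester lie to the right, among those raised by LPS, and both axes share the Veh_LPS libraries.

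The comparison of D2HG_LPS with Veh_N shows how far the ester-treated cells lay from unstimulated cells. All 19 cytokine genes and all 16 chemokine genes were higher than in Veh_N, by either adjustment. Il6 stood at a log2 fold change of 10.20 ± 0.22, Il12b at 9.83 ± 0.23, Il1b at 9.37 ± 0.21, Tnf at 7.66 ± 0.11, Il10 at 5.02 ± 0.15, Nos2 at 10.29 ± 0.12, Acod1 at 10.22 ± 0.14, Cxcl10 at 10.32 ± 0.14, Ccl5 at 10.04 and Ccl2 at 5.48. Counting intervals (95%) were 9.30 to 11.49 for Il6 and 8.93 to 11.12 for Il12b. The uridine phosphorylase gene Upp1 (10.11, interval 8.91 to 12.15 from 4 counts in Veh_N, and 11.20 without Veh_N replicate 2), Serpina3g (10.01) and the activation marker Cd69 (9.89) were among the largest rises. Bcl2a1a and Mir155hg, the host gene of microRNA-155, had 0 counts in Veh_N and were at least 73.4-fold and 60.3-fold higher against the floor of 3 counts per library. Interferon-stimulated genes were higher in 42 of 42 cases and integrated stress response genes in 18 of 22 (edgeR and DESeq2 called none lower, none had a lower value at an unadjusted p below 0.05, and limma-voom called 1 lower), while cell cycle genes were lower in 29 of 40 and higher in 9. Cxcr4 (-6.33), the exchange factor gene Rasgrp3 (-6.05) and Arhgap19 (-5.53) were among the genes with the largest falls, and D2hgdh was again lower (-1.38 ± 0.15). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4114 genes were higher and 4321 lower, 72.6% of those tested. Of 37 lists 19 were called, and the cytokine list stayed called with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.033), while chemokines (0.0879), interferon-stimulated genes (0.231), the integrated stress response (0.231) and the cell cycle (0.233) were among the 18 that did not. The share of calls that were higher was 48.8%, against 34.4% with upper-quartile scaling (median shift -0.30) and 23% with library totals alone (median shift -0.61).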

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

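Scaling by library totals, the corrections for length and GC content, the sums of isoforms and the fits without 2 libraries were tests chosen after the result was seen.

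Under LPS 8587 genes were called, and the other settings run gave 6671 (at least 10 CPM in 3 libraries) to 9701 (library totals), except 5298 with glmTreat at 1.5-fold, which asks for a larger change. For D2HG_LPS against Veh_N the 8435 calls became 6566 to 9461, and 5017 with glmTreat. The 245 calls with the ester moved further: 515 with DESeq2, 450 with only the 2 groups compared, 508 with the length correction, 610 with the GC correction, 565 without Veh_LPS replicate 3 and Veh_N replicate 1 together, and 14 with glmTreat at 1.5-fold. Leaving out 1 library gave 64, 92 and 80 without D2HG_LPS replicate 1, 2 or 3, 86, 148 and 151 without Veh_LPS replicate 1, 2 or 3, and 501, 143 and 387 without Veh_N replicate 1, 2 or 3. With RLE size factors, upper quartile, no low-count filter, the 10 CPM filter, limma-voom, robust=FALSE, library totals and isoform sums it stayed between 203 and 314. Veh_N libraries do not enter this contrast, so leaving one out can act only through the filter, the scaling and the shared estimate of the spread. The median shift of fold changes from the main fit was 0 without Veh_N replicate 1, 2 or 3. The loss with glmTreat follows from its threshold, and beyond that the cause was not tested.

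The number of ester calls against their LPS call (179) was 381 with DESeq2, 321 with only the 2 groups compared, 368 with the length correction, 426 with the GC correction, 406 without Veh_LPS replicate 3 and Veh_N replicate 1, and 13 with glmTreat. Without 1 library it was 46, 65 and 60 (D2HG_LPS replicate 1, 2 or 3), 66, 107 and 111 (Veh_LPS) and 369, 104 and 278 (Veh_N), and in other fits without the replicate block it ran from 152 to 225. The cause was not tested.

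Of the lists, 18, 9 and 19 were called for LPS, the ester and both against Veh_N. With an estimated correlation 1, 2 and 1 were, with directional fry 32, 5 and 32 and with mixed fry 36, 24 and 36. Fry asks whether members change at all, not whether they change more than other genes. For the ester, the other settings run for lists gave 8 to 13. The cytokine list with the ester had Benjamini-Hochberg adjusted p = 0.123 with an estimated correlation, against 4.61e-05 to 0.0124 over the other alternatives run for it. For all 9 lists called with the ester, the estimated correlation gave the highest adjusted p of the alternatives.

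Replicate numbers are shared between the groups, but the labels do not say that a number marks a shared animal or day. Deviations of same-numbered D2HG_LPS and Veh_LPS libraries correlated at 0.036, -0.137 and -0.131. Against Veh_N, same-numbered libraries gave -0.029, -0.03 and 0.191 for D2HG_LPS and -0.218, 0.096 and -0.456 for Veh_LPS. Pairs with different numbers ran from -0.391 to 0.529. The deviations were taken within groups of 3 and hold the trend with length, so they cannot show whether a number marks a shared animal or day. With the replicate number as a block, 93 genes were called with the ester, 67 of them against their LPS call, while 8283 were called for LPS and 8117 for D2HG_LPS against Veh_N. The number of lists called was 18, 9 and 18 under the block.

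Of 59 genes named as called with the ester, 33 were called in all 9 fits that left out 1 library, and none of the 59 changed direction in any setting. Of genes not called with the ester, Il10 was called with the length correction (-0.327) and without the 2 libraries (-0.326), while Gbp6, Mki67 and Tpx2 were each called in 2 of these 9 fits, without Veh_N replicate 1 or 3, and in 6, 6 and 4 of 15 other settings. Il1b had log2 values of -0.0227 with DESeq2, -0.0235 with RLE, -0.0521 with the length correction, and -0.1167 (without D2HG_LPS replicate 3) to 0.1193 (without D2HG_LPS replicate 2) over the fits that left out 1 library. Ccl2 turned to 0.0176 with upper quartile, 0.0034 with the 10 CPM filter, 0.0563 with library totals, 0.0634 with the GC correction and 0.0115 without the 2 libraries (-0.0495 without Veh_LPS replicate 1 to 0.0211 without Veh_LPS replicate 2). Cxcl10 turned to 0.0085 with upper quartile, 0.0468 with library totals and 0.0219 with the GC correction (-0.0332 without Veh_LPS replicate 3 to 0.0013 without Veh_LPS replicate 2). Hif1a turned to 0.001 without the 2 libraries and to 0.0011 without Veh_LPS replicate 3 (lowest -0.2238). Idh2 turned to -0.0018 and -0.0039 with the length and GC corrections, -0.0315 without the 2 libraries and -0.0314 without Veh_LPS replicate 3 (highest 0.0828, without Veh_LPS replicate 2). For LPS, Idh2 turned to -0.27 with upper quartile, -0.0365 with the 10 CPM filter, -0.61 with library totals and -0.0128 with the length correction. These values lie near 0, except for Idh2 under other scalings, which shift all genes, and the cause was not tested. At 9451258 to 13759935 counts per library, genes with few counts were not tested at all, and in the simulated data edgeR recovered 51.5% of 66 genes changed 1.5-fold between D2HG_LPS and Veh_LPS.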

Other observations

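The genes of the next paragraph other than F10, Thbs1 and Cd300lb were chosen after their values were seen, as were the tests on the shared libraries, on a uniformly weaker response and on the octyl carrier.

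Between D2HG_LPS and Veh_LPS several genes of secreted and surface proteins changed that the report does not describe. Ptx3, which encodes the pattern recognition protein pentraxin 3, fell from 6.32 to 1.48 CPM (log2 fold change -2.08 ± 0.25), and the selectin gene Sele from 9.50 to 3.33 CPM (-1.50 ± 0.21). The coagulation factor gene F10 (-0.75 ± 0.09) and the matrix gene Thbs1 (-0.84 ± 0.14) fell as well. Olr1, which encodes a scavenger receptor, rose from 4.18 to 11.8 CPM (1.48 ± 0.20), next to Pdgfa (1.06 ± 0.18) and the activating receptor Cd300lb (0.91 ± 0.12). Odc1, the gene of the enzyme that makes putrescine, rose from 44.0 to 89.2 CPM (1.02 ± 0.11) and the spermine oxidase gene Smox by 0.63 ± 0.10. No list of polyamine genes was tested. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 9.83e-04 for Ptx3 and F10, 0.00518 for Sele, 0.00206 for Olr1, 7.39e-04 for Odc1, 0.00214 for Cd300lb, 0.00728 for Smox and 0.00781 for Pdgfa and Thbs1. Without D2HG_LPS replicate 1 the calls of Thbs1 (-0.81), Pdgfa (0.975) and Smox (0.63) were lost, and DESeq2, whose filter on low counts left Ptx3 without an adjusted p, did not call it (-2.12).

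The first pattern is a trend of the ester's fold changes with transcript length (Spearman's rho -0.318 over 6693 genes) and GC content (0.339). Without Veh_LPS replicate 3 the rho was -0.037, so the trend is consistent with a deviation of that library, whose deviations from the mean of its own group rose with length (rho 0.59). As the source of the calls the trend was argued against, since 98.4% of the 245 genes stayed called in the same direction under the length correction, which brought the rho to 0.003. What set libraries apart, such as RNA quality or a library batch, stays open: the labels give neither, and the noncoding transcript left out of the tests was high in Veh_LPS replicate 3 (2.075%) and Veh_N replicate 1 (2.25%), whose deviations rose with length, but also in D2HG_LPS replicate 1 (1.713%, rho 0.069).

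The next pattern is that ester calls run against the LPS response. A covariance of -0.181 lay below the lowest of 100 values (-0.042) simulated with an unchanged ester group. Each gene was drawn on its own there, without deviations that run across genes within a library. Gene-wise noise in the shared Veh_LPS libraries alone is thus argued against. Library-wide deviations in them, such as those with length (rho 0.59 and -0.612 in Veh_LPS replicates 3 and 2), were not simulated and stay open. A uniformly weaker response to LPS would lower all genes that LPS raised. It is argued against by the 25.6% of LPS-raised genes among the calls that were higher (33 against 96 lower, 57 against 279 by DESeq2 and 27 against 134 by RLE). At an LPS log2 change of 5 or more, though, only 2 were higher against 34 lower. Among LPS-raised genes glmTreat called 2 lower and 0 higher. Of the genes fixed beforehand with an LPS change above 5, Il6 (-0.69 ± 0.11) and Il12b (-0.81 ± 0.12) were called lower. Il1b (0.01 ± 0.12), Tnf (-0.09 ± 0.08), Cxcl10 (-0.02 ± 0.09), Ccl2 (-0.01 ± 0.16), Acod1 (-0.12 ± 0.09), Nos2 (-0.20 ± 0.07) and Il10 (-0.27 ± 0.11) were not. A fall of equal size in these genes is thus argued against. A weaker response of part of the strongly raised genes stays open. A treatment effect stays open as a hypothesis and was not separated from a batch of the groups: the 58.8% of ester calls kept without Veh_LPS replicate 3, and 26.1% without D2HG_LPS replicate 1, depend on the libraries left and do not test it. Splitting the 6 libraries of the 2 groups into 3 and 3, in fits of these alone, gives 10 splits, too few for a share under 0.05, and only the real one (1) reached 450 calls, the highest other 0, as for LPS (1 split, 8203, highest other 0) and D2HG_LPS against Veh_N (1 split, 8368, highest other 0).

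The last pattern is that the heat shock list was higher and the cholesterol synthesis list lower with the ester, next to rises of single genes such as Plin2, Hilpda and Trib3. A candidate source is the octyl carrier of the ester, not D2HG, since the ester brings an octyl group into the cell as well. The number of groups given an octyl ester without D2HG was 0, so the 2 cannot be told apart in these samples, and no group shows the ester without LPS. The biological reading, that D2HG itself changed these genes, stays equally open as an untested hypothesis.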
